A study of Mus musculus with 12 samples.

How the data were processed

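The study measured RNA of splenic T cells, CD25-positive Treg and CD25-negative Tconv, from NOD and B6.H2g7 mice on Affymetrix expression arrays, with 12 arrays in 4 groups of 3. Per the labels, each array took RNA of 3 mice aged 6 weeks. Cells were enriched magnetically and then sorted in 2 passes as CD4+ cells without CD8a, CD11b, CD69 and B220, and with or without CD25. RNA was extracted with Trizol and amplified in 2 rounds before biotin labelling, per the labels' protocols. The replicates of a group are independent pools, per the series text.

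The deposited table holds 1 intensity per probe set and array on a linear scale, normalized by the authors with RMA, per the series text and the submitters' processing notes. The RMA software and its version are not given in the sources used here. The linear scale was read from the values: the lowest intensity on any array was 5.78 and the highest 27207. The authors averaged the intensity over replicates and took the ratio of Treg to Tconv per strain, per the series text. Here log2 was taken of the deposited values, with no further normalization, pseudocount or filter. Every array column was mapped to a sample. Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. Of these, 34945 name 1 gene in the platform annotation, 932 name several and 9160 are unnamed there. The Entrez IDs of 34741 matched the RefSeq gene table of GRCm38.p6, which changed 0 symbols; its coordinates were used once, to take the H2 region from H2-Ke6 to H2-M3. A gene was represented by its probe set of the highest mean over all 12 arrays among those naming it alone, which gave 18193 genes. Other probe sets of a gene can disagree, and the text says where for several named genes, a comparison made after the results were seen. The deposited values hold no detection calls. A level is called dim in the text where the group mean lies under 5.28, the 25th percentile of the probe set means; no fold is given there, since the size of such a change, and its rank, is uncertain.

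Tests were run with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group, eBayes with default settings). All 12 arrays shared 1 estimate of the spread per probe set, since each group held 3 arrays. The comparisons were Treg against Tconv in B6g7, in NOD and averaged over both strains, the difference between strains in that change, and NOD against B6g7 in Tconv and in Treg. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. Changes are log2 differences of group means with the standard error of the fit. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so no such test was run for single genes. On simulated data made from the real means and spreads of 45037 probe sets, the fit for B6g7 Treg against Tconv recovered 46%, 94% and 100% of 50 planted log2 changes of 0.585, 1 and 2. For the difference between strains it recovered 16%, 86% and 98%. The simulated noise was independent between arrays and probe sets, and few changes were planted. These shares therefore need not hold for the real arrays, whose deviations correlated.

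The text names, by a rule fixed before the data were examined, the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose 3 arrays per group do not overlap (for the difference between strains, among called genes). It also names Foxp3, Il2ra, Cd4, Cd69, Itgam, Cd8a, Ptprc, Ctla4, Il2 and Il7r, and the 4 members of smallest p of each gene list. Other list members in the text were chosen after their values were seen, and of the names by the rule some are left out for brevity.

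The 25 gene lists were written from textbook knowledge before the data were examined: Treg-associated genes, genes lower in Treg, quiescence and naive T cell genes, chemokine receptors and adhesion, costimulation and inhibitory receptors, cytokines and effectors, cytokine receptors and JAK-STAT, T cell receptor signalling, T helper transcription factors, immediate early genes, cell cycle, interferon response, apoptosis and survival, candidate genes of Idd (diabetes susceptibility) regions, MHC region genes, sex-linked genes, and markers of B cells, plasma cells, CD8 T cells, NK and innate-like T cells, monocytes and macrophages, dendritic cells, neutrophils, erythroid cells and platelets, and stromal and endothelial cells. Member calls were counted over all probe sets and adjusted over the list alone. The 24 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists within a comparison. The set test named in the text is camera with the preset correlation. Of 44 calls so made over 6 comparisons, 14 held with an estimated correlation.

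The labels give replicates 1 to 3 in each group. Whether these numbers pair arrays was checked by correlating the arrays' deviations from their group means over probe sets. Same-numbered NOD Treg and NOD Tconv arrays correlated with 0.564, 0.315 and 0.401, and same-numbered Treg arrays of the strains with 0.671, 0.338 and 0.302, so the numbers pair these groups by the data, while the labels state no pairing. With the replicate block, 2362 instead of 1443 probe sets were called for NOD and 2184 instead of 1468 for the strain comparison in Treg. In the other comparisons of 2 groups at least 1 pair did not correlate above 0.1.

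Alternatives fixed before the data were examined were repeated quantile normalization, median centring, a filter at the median log2 level of 6.43, another variance model (trend and robust), array weights, the arrays of the compared groups alone, the replicate block, a 2-fold minimum, the authors' ratio without a test, and leaving out each array in turn. For correlations and lists they were other probe set rules, ratios of mean intensities and other set tests. Added after seeing the data were fits without the 4 arrays numbered replicate 1 and with the actin 3' minus 5' difference as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.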

Results

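Gene expression was measured in regulatory T cells (Treg, CD4+CD25+) and conventional T cells (Tconv, CD4+CD25-) sorted from the spleens of 2 mouse strains. NOD mice develop autoimmune diabetes. B6.H2g7 mice, written B6g7 here, are B6 mice congenic for the MHC haplotype of NOD. The 4 groups, B6g7 Tconv, B6g7 Treg, NOD Tconv and NOD Treg, held 3 arrays each, 12 in all. Each array took RNA pooled from 3 mice aged 6 weeks, and the series text describes the pools of a population as independent. The question stated for the series was how the ratio of Treg to Tconv expression compares between the strains. Per the labels, 94%, 96% and 96% of the sorted B6g7 Treg cells and 89%, 95% and 95% of the NOD Treg cells were Foxp3+. The median intensity per array lay between 83.9 and 88.6, and arrays of one group correlated with r between 0.983 and 0.9962. The number of arrays limits the precision of each value.

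The levels of Foxp3 and Il2ra followed the labels in every array. Foxp3, the transcription factor that defines Treg cells, had a mean log2 intensity of 11 ± 0.27 (SD, n = 3) in B6g7 Treg and 5.68 ± 0.14 in B6g7 Tconv. In NOD it was at 11.05 ± 0.33 in Treg and 5.91 ± 0.34 in Tconv. Il2ra, which encodes CD25, stood at 11.02 ± 0.08 against 5.69 ± 0.17 in B6g7, and at 10.81 ± 0.11 against 5.75 ± 0.04 in NOD. Cd8a and Itgam, whose proteins the sort excluded, and Ptprc did not pass the test in any of the 6 comparisons. Cd69, whose protein the sort also excluded, was called higher in NOD in Tconv and in Treg.

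**Figure D1:**
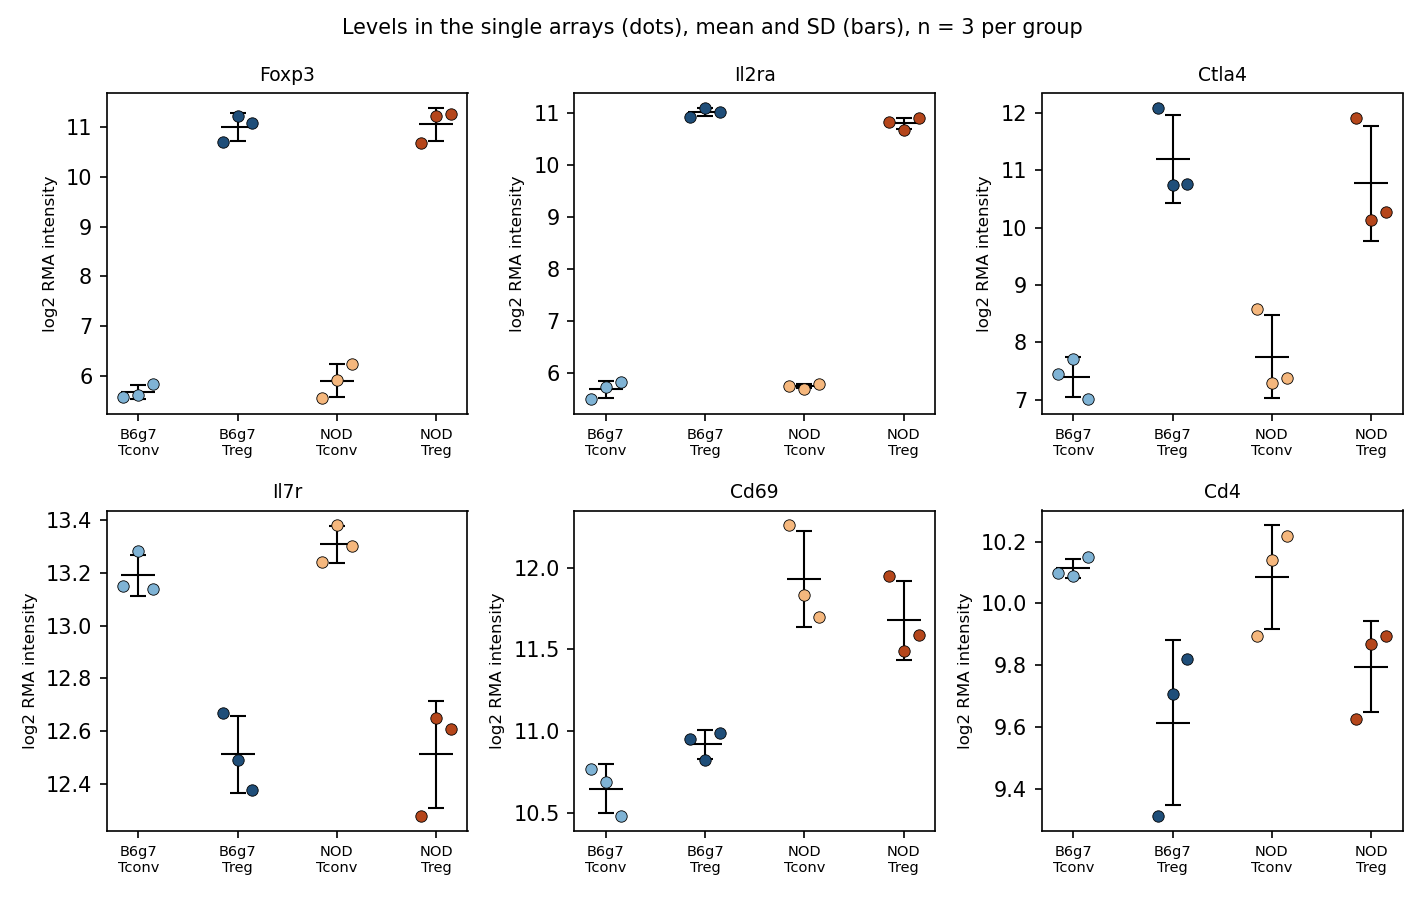
Log2 RMA intensity of Foxp3, Il2ra, Ctla4, Il7r, Cd69 and Cd4 in the single arrays (dots) of the 4 groups, with the mean and SD of n = 3 arrays (bars); each panel has its own scale, which does not start at 0. Foxp3 and Il2ra lie near 11 in Treg and under 6.5 in Tconv of both strains, Il7r is lower in Treg, and Cd69 is higher in NOD.

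Control transcripts differed within the groups. The 3' minus 5' difference of the actin control probe sets, which grows as RNA is shortened, ranged from 2.66 to 4.70 on the log2 scale. Its group means were 3.98 ± 0.40 (SD, n = 3) in B6g7 Tconv, 3.83 ± 1.03 in B6g7 Treg, 3.67 ± 0.65 in NOD Tconv and 4.15 ± 0.76 in NOD Treg. In B6g7 Treg, NOD Tconv and NOD Treg the array numbered replicate 1 had the lowest value, at 2.66, 2.97 and 3.29. Ctla4 was highest in the same arrays, at 12.09, 8.59 and 11.92, against a highest value of 10.77, 7.37 and 10.27 in the other arrays of those groups.

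**Figure D2:**
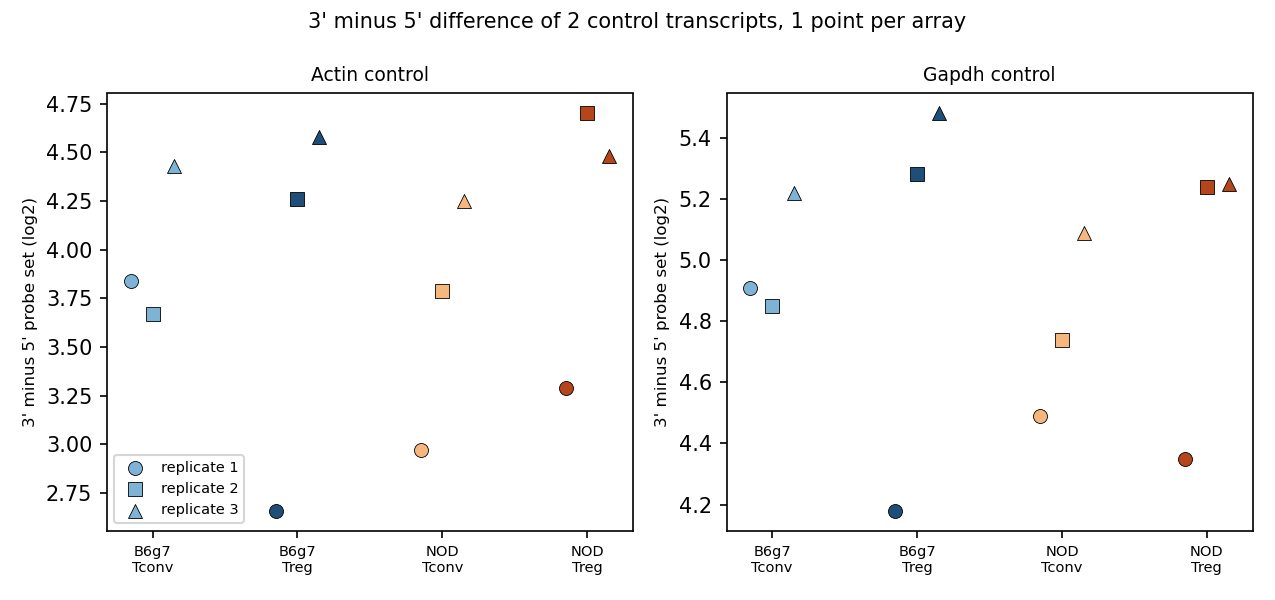
The 3' minus 5' difference (log2) of the actin and Gapdh control probe sets in each of the 12 arrays, with 1 point per array and the replicate number given by the marker; the axes do not start at 0. For actin, replicate 1 lies at 2.66 in B6g7 Treg, 2.97 in NOD Tconv and 3.29 in NOD Treg, below the other arrays of those groups.

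In B6g7 mice, Treg cells had far more RNA of the known Treg genes than Tconv cells. Il2ra was 40.4-fold higher in Treg (log2 change 5.34 ± 0.10, SE, n = 3 per group, adjusted p = 3.09e-11) by its brightest probe set and changed by 1.85 (adjusted p = 0.00479) by the other, and Foxp3 was 39.9-fold higher (5.32 ± 0.20, adjusted p = 1.66e-08). Next came Plagl1, a zinc finger transcription factor, at 22.9-fold and Itgb8, an integrin chain that takes part in activating latent TGF-beta, at a log2 change of 4.38 from a dim Tconv level of 4.66. Klrd1, a chain of NK cell receptors, had the largest decrease, 19.4-fold lower in Treg (-4.28 ± 0.22, adjusted p = 1.52e-07), followed by Lypd6b at 13.3-fold and the cAMP phosphodiesterase Pde3b at 12.2-fold. The other genes among the 12 largest rises were the transcription factor genes Ikzf2 (3.91) and Ikzf4 (3.38), the inhibitory receptor gene Ctla4 (3.81), Gpr83 (3.60), the MAP kinase phosphatase gene Dusp4 (3.57), Nrp1 (3.56), the receptor chain gene Il2rb (3.51) and the Rac activator gene Tiam1 (3.42), as log2 changes. Lower in Treg were also Lrrc75b (-3.54), the amyloid precursor gene App (-3.51), A530021J07Rik (-3.47), Il1rl2 (-3.47), Atp8b4 (-3.45), the hypoxia-induced factor gene Epas1 (-2.93), Pdlim4 (-2.93), Dapl1 (-2.83) and Pxylp1 (-2.77), of which Lrrc75b, A530021J07Rik and Il1rl2 had dim Treg levels of 4.35, 3.66 and 5.23. Il7r, the receptor gene for the survival cytokine IL-7, was lower in Treg by a small margin (-0.68 ± 0.11, adjusted p = 0.00374). Cd4 (-0.50 ± 0.14, adjusted p = 0.0744), Cd69 (0.27 ± 0.15, adjusted p = 0.566) and Il2 (-0.21 ± 0.12, adjusted p = 0.576) did not pass the test. In all, 1519 probe sets were called, 917 higher and 602 lower in Treg, which stood for 517 and 310 genes. With only the arrays of these groups 976 were called, with the replicate block 2286, with array weights 3460, 1775 higher and 1685 lower, and with the actin difference as a covariate, an alternative chosen after seeing the data, 2496.

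The NOD comparison was led by many of the same genes. Foxp3 was 35.3-fold higher in NOD Treg than in NOD Tconv (5.14 ± 0.20, SE, n = 3 per group, adjusted p = 2.28e-08), Il2ra 33.5-fold (5.07 ± 0.10, adjusted p = 5.84e-11; 1.58, adjusted p = 0.0149, by its other probe set) and Ntn4, a netrin gene, 31.1-fold (4.96 ± 0.15, adjusted p = 4.15e-09). Lrrc75b (-4.60 ± 0.22, adjusted p = 1.34e-07) and Pdlim4 (-3.95 ± 0.20, adjusted p = 1.70e-07) were lower in Treg, where their levels of 4.52 and 5.10 were dim, so the size of these changes is uncertain. Other large increases were those of Itgb8 (4.54, from a dim level of 4.77), Plagl1 (4.40), Dusp4 (3.46), Itih5 (3.43), Ikzf4 (3.33), Il2rb (3.24), Gpr83 (3.22), Ikzf2 (3.17) and Rgs16, a regulator of G protein signalling (3.04). Lypd6b (-3.77), Klrd1 (-3.68), App (-3.19), Il1rl2 (-3.09), the neuropeptide receptor gene Vipr1 (-3.02), Atp8b4 (-2.96), Pde3b (-2.94), Dapl1 (-2.62), Pxylp1 (-2.56) and Tdrp (-2.55) were lower in Treg. Ctla4 was 8.12-fold higher (3.02 ± 0.50, adjusted p = 0.00351) and Il7r lower (-0.80 ± 0.11, adjusted p = 0.00118). Cd4 (-0.29, adjusted p = 0.47), Cd69 (-0.26, adjusted p = 0.672) and Il2 (-0.21, adjusted p = 0.615) did not pass. The test called 1443 probe sets, 941 higher and 502 lower in Treg, for 520 and 277 genes. With the replicate block, in which the numbers pair the NOD arrays, 2362 probe sets were called, and with the actin difference as a covariate 2225.

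Averaged over both strains, 28 of the 30 measured Treg-associated genes were higher in Treg and none was lower; adjusted over the list alone, 29 were higher. Foxp3 (5.23 ± 0.14, SE, 6 arrays per population), Il2ra (5.20 ± 0.07), Plagl1 (4.46 ± 0.13) and Itgb8 (4.46 ± 0.16, dim in Tconv) led the list, and its set test gave an adjusted p of 5.49e-68 (adjusted p = 9.49e-07 with an estimated correlation). Costimulation and inhibitory receptor genes also rose as a group, with 14 of 30 higher and 0 lower; adjusted over the list alone, 17 were higher and 1 lower. Among them were Tnfrsf4 (2.68), which encodes OX40, Cd200 (1.78), Cd86 (1.39), a ligand of CD28 and CTLA-4, and Tnfrsf18 (1.32), which encodes GITR. Their set test gave an adjusted p of 7.88e-15 (adjusted p = 1.92e-04 with an estimated correlation). Of 34 cytokine receptor and JAK-STAT genes, 10 were higher and 2 lower (16 and 4 adjusted over the list alone, set test adjusted p = 1.93e-07, adjusted p = 0.0086 with an estimated correlation). Cish, a STAT target that restrains cytokine signalling, was higher by 1.89, while Tgfbr2 (-0.91) and Il7r (-0.74) were lower. Of 27 apoptosis and survival genes, 8 were higher and 1 lower (13 and 1 adjusted over the list alone, set test adjusted p = 1.93e-07, adjusted p = 0.0176 with an estimated correlation). The higher ones included the pro-apoptotic gene Pmaip1 (2.49), the survival genes Bcl2l1 (0.77) and Birc3 (0.75) and the caspase gene Casp4 (1.05), and the lower one was Fasl (-1.25).

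The genes listed as lower in Treg fell as a group: 8 of 14 were lower, and Id3 (0.83) was higher. Adjusted over the list alone, 9 were lower and 2 higher, and the set test gave an adjusted p of 6.38e-10 (adjusted p = 9.82e-04 with an estimated correlation). Pde3b (-3.28), Dapl1 (-2.73), Igfbp4 (-1.57) and Themis (-1.09), a gene of T cell receptor signalling, had the largest decreases of this list. Of 14 quiescence and naive T cell genes, 3 were lower, by either adjustment for multiple tests (3 adjusted over the list alone): the homing receptor gene Ccr7 (-0.90), Il7r (-0.74) and Lef1 (-0.76). That list's set test gave an adjusted p of 0.00351, which did not hold (adjusted p = 0.139 with an estimated correlation). Of 29 T cell receptor signalling genes, 4 were lower and 0 higher, namely Themis, Malt1 (-0.59), Grap2 (-0.56) and Cd4 (-0.40 ± 0.10, adjusted p = 0.0262). Adjusted over the list alone, 11 were lower; the set test gave an adjusted p of 4.96e-04 (adjusted p = 0.157 with an estimated correlation). The Cd4 call was lost in 6 of the 12 fits without 1 array, with a highest adjusted p of 0.0763, and the other Cd4 probe set was at 0.10 (adjusted p = 0.829).

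Of 17 T helper transcription factor genes, 8 were higher and 3 lower in Treg (8 and 4 adjusted over the list alone). Ahr (1.56), Maf (1.37), Eomes (1.24) and Irf4 (0.99) were higher, while Id2 (-1.59), Tbx21 (-1.46, dim in B6g7 Treg), which encodes T-bet, and Runx3 (-0.99) were lower; the set test gave an adjusted p of 0.00885 (adjusted p = 0.0715 with an estimated correlation). Of 28 cytokine and effector genes, 6 were higher and 6 lower (7 and 8 adjusted over the list alone, set test adjusted p = 0.972). Lta (1.22), Penk (0.98), Ebi3 (0.67) and Fgl2 (0.66, dim in all groups) were higher, and Ccl5 (-1.34), Fasl (-1.25), Il21 (-1.0) and Ifng (-0.79) lower. Of 25 chemokine receptor and adhesion genes, 4 were higher and 2 lower (5 and 2 adjusted over the list alone, set test adjusted p = 0.299). Itgae (1.80), which encodes CD103, and Ccr6 (1.30) were higher, and Ccr7 (-0.90) and Cxcr3 (-0.78) lower. Of 24 immediate early genes, 7 were higher and 0 lower (9 and 2 adjusted over the list alone), among them Nr4a3 (1.04), Nr4a1 (0.98) and Egr2 (0.67), which T cell receptor signals induce, and Dusp1 (0.95). Their set test gave an adjusted p of 2.06e-04 (adjusted p = 0.225 with an estimated correlation).

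Most markers of other cells were not called between Treg and Tconv. Of 22 B cell markers, 6 were higher in Treg and 0 lower (7 and 1 adjusted over the list alone): H2-Aa (1.65), Cd79b (0.79), Cd72 (0.79), H2-Eb1 (0.74), Bank1 (0.62) and Cd74 (0.31). That set test gave an adjusted p of 0.00885 (adjusted p = 0.309 with an estimated correlation), and 4 members stand in another list as well. Of 23 genes of the MHC region, 6 were higher (9 adjusted over the list alone): H2-Ob (1.66), H2-Aa, Lta, H2-Eb1, H2-Oa (0.61) and H2-DMa (0.55), of which all but Lta belong to antigen presentation by MHC class II. Their set test gave an adjusted p of 1.61e-05 (adjusted p = 0.139 with an estimated correlation). The B cell genes Cd79a (-0.05), Ms4a1 (0.03) and Cd22 (-0.12) did not pass the test, with adjusted p of 0.913, 0.965 and 0.776, and the sort had excluded cells with B220. Of 16 NK and innate-like T cell markers, 3 were higher, Il2rb (3.38), Eomes (1.24) and Fcer1g (0.30), and Klrd1 (-3.98) was lower (3 and 1 adjusted over the list alone). The set test gave an adjusted p of 0.554, and fry's test for changes in either direction an adjusted p of 4.62e-11. Of 19 monocyte and macrophage markers 1 was lower (Fcgr3, -0.67), and none of 11 neutrophil and 11 stromal and endothelial markers was called.

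The averaged comparison called 2632 probe sets, 1552 higher and 1080 lower in Treg, for 812 and 552 genes. Ntn4 (4.03), Itih5 (3.36) and Ikzf4 (3.36) were also among the 12 largest increases, and Lrrc75b (-4.07), Klrd1 (-3.98), Lypd6b (-3.75) and Pdlim4 (-3.44) had the largest decreases, with dim levels in Treg for Lrrc75b and, in NOD, Pdlim4. Of 82 called named genes and list members with other probe sets, 45 had at least 1 other called in the same direction and 0 in the opposite one. With array weights there were 4796, with nearly as many lower (2392) as higher (2404), and with the actin covariate 4138.

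The Treg to Tconv changes ran in parallel in both strains. Across 18193 genes the log2 changes of B6g7 and NOD correlated with r = 0.731 (Spearman's rho 0.303), and across the 1091 genes called in either strain with r = 0.899 (rho 0.852); genes are not independent replicates, and the comparisons share no arrays. Of the genes higher in Treg, 356 were called in both strains, where independent lists would share 14.8, and of the genes lower in Treg 176, against 4.72. Il18r1, a receptor chain gene for IL-18, was the 1 gene called in opposite directions, -0.66 in B6g7 and 1.04 in NOD.

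**Figure D3:**
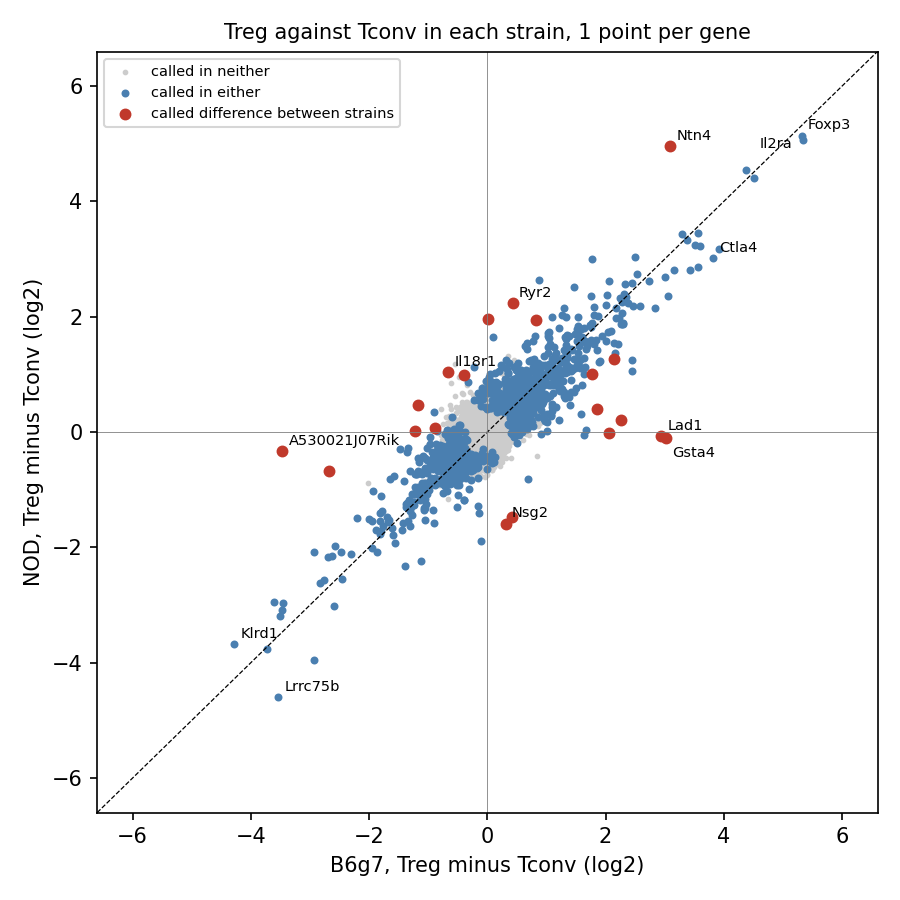
Log2 change from Tconv to Treg in B6g7 (horizontal) and NOD (vertical), with 1 point per gene; blue points were called in either strain, red points are the 20 genes with a called difference between strains, and the dashed line marks equal changes. Foxp3 and Il2ra lie on the line above 5, and Gsta4 and Lad1 lie near 3 in B6g7 and near 0 in NOD.

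The Treg to Tconv change differed between the strains in 20 genes, tested directly as a difference of the 2 changes. Gsta4, a glutathione transferase gene, and Lad1, which encodes an anchoring filament protein, were higher in B6g7 Treg (3.02 ± 0.10 and 2.94 ± 0.27, SE, n = 3 per group) but not in NOD Treg (-0.10 ± 0.10 and -0.07 ± 0.27). The differences, NOD minus B6g7, were -3.12 ± 0.14 (adjusted p = 1.11e-06) and -3.00 ± 0.38 (adjusted p = 0.00629). Hopx (-2.05 ± 0.16, adjusted p = 9.94e-05) and Khdc1a (-2.07 ± 0.19, adjusted p = 2.49e-04) were likewise higher in Treg of B6g7 (2.26 and 2.06) with values of 0.21 and -0.01 in NOD. P2rx7, an ATP-gated channel gene, rose by 1.86 in B6g7 Treg against 0.39 in NOD (difference -1.47 ± 0.16, adjusted p = 0.00171). Nsg2 (-1.90) and the sialyltransferase gene St6galnac2 (-1.89) were lower in NOD Treg than in NOD Tconv (-1.59 and -1.48) and changed by 0.31 and 0.41 in B6g7. Ntn4 was higher in Treg of both strains, with the larger change in NOD (difference 1.87 ± 0.21, adjusted p = 0.00216). The calcium channel gene Ryr2 (1.80), Il18r1 (1.70), Irak1bp1 (1.95) and Bcl2l15 (1.39) also had a more positive change in NOD. Levels were dim in all groups but B6g7 Treg for Khdc1a, in all but NOD Treg for Irak1bp1, and in B6g7 Treg for Bcl2l15.

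**Figure D4:**
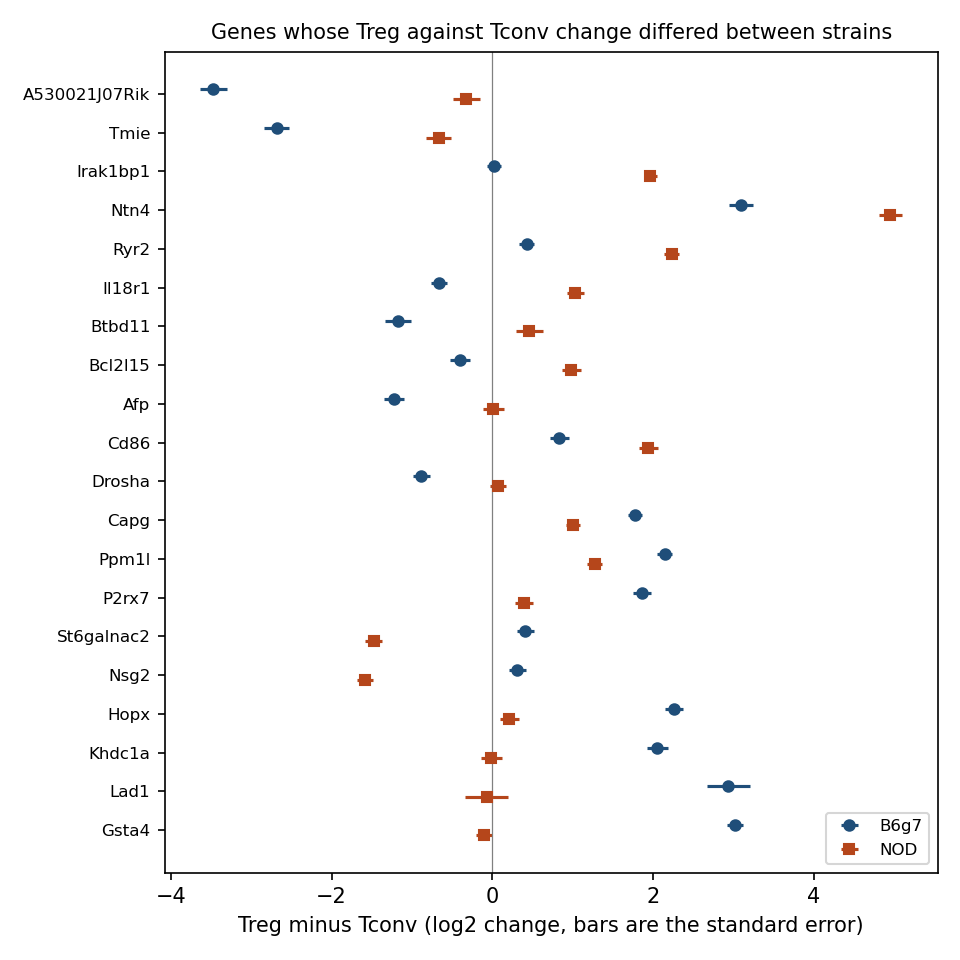
Log2 change from Tconv to Treg of the 20 genes with a called difference between strains, in B6g7 (circles) and NOD (squares), with standard errors from the fit (n = 3 per group). Gsta4, Lad1, Khdc1a and Hopx are above 2 in B6g7 and near 0 in NOD, and Irak1bp1 and Ryr2 are near 2 in NOD and below 0.5 in B6g7.

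A further pair, A530021J07Rik (3.15 ± 0.24, adjusted p = 8.38e-05) and Tmie (2.02 ± 0.21, adjusted p = 0.00138), was lower in Treg of B6g7 (-3.47 and -2.69) with smaller values in NOD (-0.33 and -0.67), though A530021J07Rik was dim in all groups but B6g7 Tconv. The calls of Btbd11 (1.63), Afp (1.24, dim in NOD), the costimulatory ligand gene Cd86 (1.11), the microRNA processing gene Drosha (0.96), Ppm1l (-0.87) and Capg (-0.77) each depended on single arrays. Of the 12 fits without 1 array, they passed in 6, 6, 2, 2, 2 and 1, with highest adjusted p of 0.0888, 0.098, 0.115, 0.116, 0.115 and 0.178. Without the 4 arrays numbered replicate 1, an alternative chosen after seeing the data, these 6 genes, Bcl2l15 (adjusted p = 0.144) and P2rx7 (adjusted p = 0.0622) did not pass. Foxp3 (-0.18 ± 0.28, adjusted p = 0.966), Il2ra (-0.27 ± 0.14, adjusted p = 0.962) and Ctla4 (-0.79 ± 0.70, adjusted p = 0.962) did not pass the test of a difference. Il21 (-1.79 ± 0.32) missed the threshold over all probe sets (adjusted p = 0.094) and passed adjusted over the list alone, in the cytokine list (adjusted p = 0.00298) and among the Idd candidates (adjusted p = 0.00138). Of the 30 Treg-associated genes Capg alone was called; adjusted over the list alone, Capg, Nrp1 (-0.69) and Tnfrsf18 (-0.63) had smaller increases in NOD. The list's set test leaned the same way (adjusted p = 0.0151) and did not hold (adjusted p = 0.112 with an estimated correlation). Of the other 23 lists with a set test none passed. The test of the difference called 42 probe sets, 24 higher and 18 lower, with 2043 at an unadjusted p under 0.05, where 2252 would be if no probe set differed. Of 15 called genes with other probe sets, 3 had another one called, in the same direction. These were A530021J07Rik (3.29), Afp (2.22, adjusted p = 0.0187, and 1.71, adjusted p = 0.0128) and Btbd11 (1.54, adjusted p = 0.0461). The further Afp probe sets were also dim in NOD, and that of A530021J07Rik in all groups but B6g7 Tconv. There were 89 calls with the replicate block, 79 with array weights, 71 with the actin covariate, 27 without NOD Treg replicate 3 and 17 among probe sets above the median level.

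Tconv cells of the strains differed by large amounts in single genes. Zfp979, a zinc finger gene, was higher in NOD Tconv than in B6g7 Tconv (log2 change 6.2 ± 0.25, SE, n = 3 per group, adjusted p = 2.47e-08) from a dim level of 3.29, and Cap1 (3.58), St6galnac2 (3.44), Bex1 (3.43), Rnf157 (3.26), the chemokine receptor gene Cxcr4 (3.06), Phactr2 (2.94) and Scpep1 (2.70) followed, with Bex1 also dim in B6g7. Trim12c (-5.45 ± 0.17, adjusted p = 4.55e-09) was lower in NOD, at a dim level of 3.57. The brightest probe set of the peptide transporter gene Slc15a2 was lower (-5.28 ± 0.21, adjusted p = 2.47e-08), while its others were at 0.02 and -0.05 (adjusted p = 0.982 and 0.94). Also lower were Trim12a (-4.83), Rab6b (-4.52), Cd200r4 (-4.06), Ifi213 (-3.90) and Trim30a (-3.06; other probe set -0.11, adjusted p = 0.91), with dim NOD levels for Trim12a, Rab6b and Cd200r4 (3.47, 5.25 and 3.69). Cd69, an early activation marker whose protein the sort excluded, was 2.44-fold higher in NOD Tconv (1.28 ± 0.15, adjusted p = 2.89e-04). Il21, a T cell cytokine gene in a diabetes susceptibility region, was higher by 1.77 ± 0.22 (adjusted p = 4.91e-04), and Pmaip1 (2.06) and Casp1 (0.84) were higher as well. Id2 was higher by its brightest probe set (1.37) and lower by another (-0.76, adjusted p = 0.00717). Ubash3a (-2.65), Runx1 (-0.99) and Capg (-0.67) were lower by their brightest probe sets, while the other Ubash3a probe set was at 0.04 (adjusted p = 0.936). Foxp3 (0.23), Il2ra (0.06), Il7r (0.12) and Il2 (0.04) did not pass, with adjusted p of 0.796, 0.912, 0.828 and 0.958.

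Of the 31 interferon response genes, 3 were lower in NOD Tconv and 0 higher (4 and 0 adjusted over the list alone): Trim30a, Rsad2 (-1.32) and Oas2 (-0.46). Their set test gave an adjusted p of 3.63e-05, which did not hold (adjusted p = 0.586 with an estimated correlation). The Rsad2 and Oas2 calls passed in 8 and 3 of the 12 fits without 1 array, with a highest adjusted p of 0.136 and 0.212. Costimulation genes were higher in 4 of 30 and lower in 0 (6 and 1 adjusted over the list alone), with Tnfrsf18 (0.62), Slamf6 (0.91), Cd27 (0.56) and Tnfrsf1b (0.63). Their set test gave an adjusted p of 0.00212 (adjusted p = 0.0778 with an estimated correlation), and the 4 calls passed in 11, 10, 7 and 7 of those 12 fits. Another Slamf6 probe set was lower (-1.50, adjusted p = 0.0032), and 1 Icos probe set that was not the brightest was lower in both populations (mean -2.12). Of the Treg-associated genes 4 were higher and Capg lower in NOD Tconv (6 and 1 adjusted over the list alone, set test adjusted p = 0.0209, adjusted p = 0.127 with an estimated correlation), among them Nrp1 (0.75 ± 0.11, adjusted p = 0.00101). Of 24 immediate early genes, 2 were higher, Cd69 and Tnfaip3 (1.18), and 4 adjusted over the list alone (set test adjusted p = 7.29e-04, adjusted p = 0.586 with an estimated correlation). The strain comparison in Tconv called 1333 probe sets, 591 higher and 742 lower in NOD, for 291 and 263 genes. With array weights 2181 were called, with the replicate block 2124 (1041 higher and 1083 lower) and with the actin covariate 2077. Of 41 called named genes and list members with other probe sets, 12 had at least 1 other called in the same direction, 2 (Slamf6 and Id2) in the opposite one, and 27 none.

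In Treg cells the strains differed in many of the same genes as in Tconv. Zfp979 (log2 change 6.05 ± 0.25, SE, n = 3 per group, adjusted p = 2.74e-08) and Bex1 (4.30 ± 0.21, adjusted p = 9.98e-08) were higher in NOD Treg from dim levels of 3.28 and 4.81, and Scpep1 was 13.9-fold higher (3.8 ± 0.33, adjusted p = 1.89e-05; other probe set 0.21, adjusted p = 0.473). Trim12c was lower (-5.61 ± 0.17, adjusted p = 3.78e-09), at a dim level of 3.53, and so was the brightest probe set of Slc15a2 (-5.63 ± 0.21, adjusted p = 1.23e-08), while its others were at 0.10 and 0.01 (adjusted p = 0.938 and 0.997). Rnf157 (3.49), Cap1 (3.28), Ryr2 (3.01), Cxcr4 (2.53) and Ifi204 (2.48) were higher in NOD, and Rab6b (-5.07), Ifi213 (-4.09), Trim12a (-4.08), Cd200r4 (-3.46), Ly6e (-3.37), Gsta4 (-3.11) and Lad1 (-3.07) lower. Of these Ifi204 was dim in B6g7 (3.17), and Rab6b, Trim12a and Cd200r4 were dim in NOD (5.26, 3.85 and 3.99). Il18r1 (1.80 ± 0.11, adjusted p = 5.10e-07), Id2 (1.58), Pmaip1 (1.36) and Casp1 (0.85) were also higher in NOD Treg, and Ubash3a (-2.40, other probe set 0.06, adjusted p = 0.953), Capg (-1.44), Cd72 (-1.42) and Runx1 (-0.99) lower. The Id2 value is that of its brightest probe set, while 2 others had a median change of -0.22, averaged over Tconv and Treg. Foxp3 (0.05, adjusted p = 0.986), Il2ra (-0.21, adjusted p = 0.505) and Ctla4 (-0.43, adjusted p = 0.927) did not pass. Cd69 was higher by 0.75 ± 0.15 (adjusted p = 0.0153), a call that was lost without B6g7 Treg replicate 2 or NOD Treg replicate 1 (highest adjusted p = 0.0662).

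Of the T helper transcription factor genes, 4 of 17 were higher in NOD Treg by their brightest probe sets, Id2, Maf (1.44), Eomes (0.93) and Runx3 (0.54), and Runx1 was lower (6 and 1 adjusted over the list alone). Their set test gave an adjusted p of 0.0413 (adjusted p = 0.189 with an estimated correlation), and the Maf and Eomes calls each passed in 8 of the 12 fits without 1 array, with a highest adjusted p of 0.0701 and 0.113. Interferon response genes were lower in 2 of 31, Trim30a (-2.93) and Rsad2 (-1.43), and in 3 adjusted over the list alone (set test adjusted p = 1.97e-04, adjusted p = 0.981 with an estimated correlation). The other Trim30a probe set changed by -0.25, averaged over Tconv and Treg. In costimulation genes 3 of 30 were higher (6 adjusted over the list alone), and the set test did not pass (adjusted p = 0.0542). The strain comparison in Treg called 1468 probe sets, 720 higher and 748 lower in NOD, for 335 and 271 genes. With only the arrays of these groups 976 were called, with the replicate block 2184, with array weights 2361 and with the actin covariate 2340. Of 33 called named genes and list members with other probe sets, 14 had at least 1 other called in the same direction and 19 none. Across the 820 genes called in either population the strain changes in Tconv and Treg correlated with r = 0.890 (rho 0.847), and across all 18193 genes with r = 0.666 (rho 0.196); 177 genes were higher and 163 lower in both, where independent lists would share 5.36 and 3.92.

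**Figure D5:**
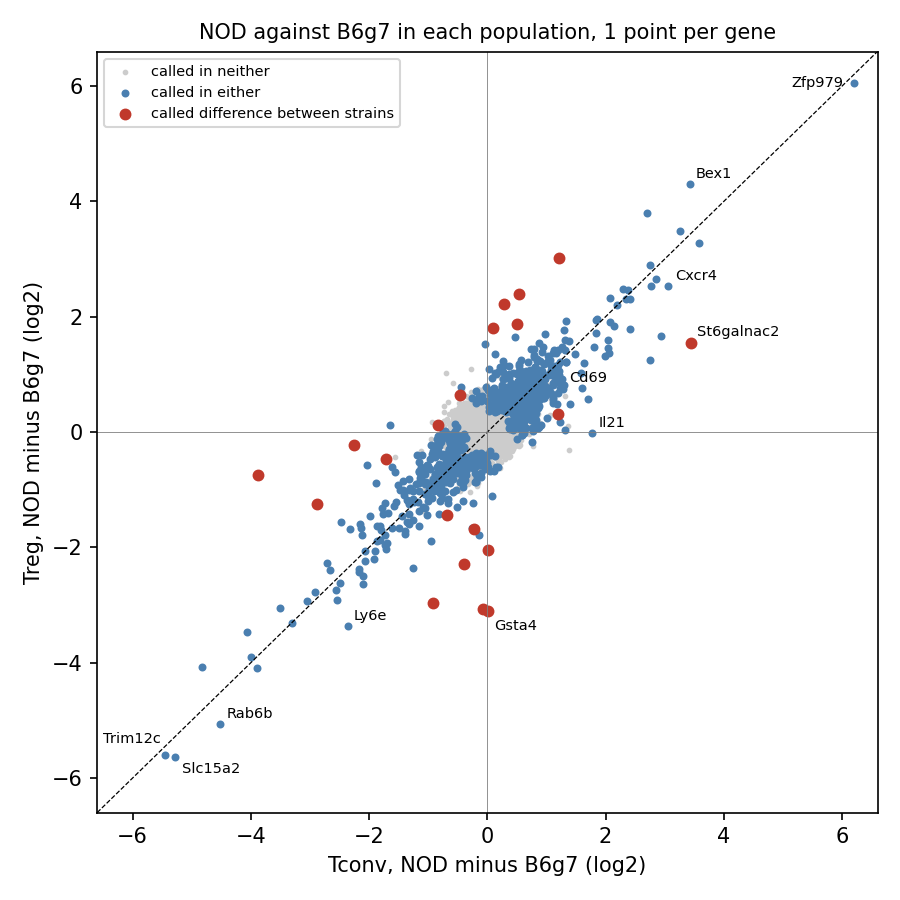
Log2 change from B6g7 to NOD in Tconv (horizontal) and Treg (vertical), with 1 point per gene; blue points were called in either population, red points are the 20 genes whose Treg to Tconv change differed between strains, and the dashed line marks equal changes. Zfp979 lies near 6 and Trim12c and Slc15a2 lie below -5 in both populations.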

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

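Of the tests in this part, the B cell test, the tests of Tconv cells on the differences larger in NOD and larger in B6g7, the comparison with the genes higher in NOD, and the fit with the actin covariate were chosen only after the result was seen. The strains differed in the Treg to Tconv change of 20 genes, by a test of the difference itself (adjusted p under 0.05, n = 3 arrays per group). As log2 differences, NOD minus B6g7, these were A530021J07Rik (3.15), Tmie (2.02), Irak1bp1 (1.95), Ntn4 (1.87), Ryr2 (1.80), Il18r1 (1.70), Btbd11 (1.63), Bcl2l15 (1.39), Afp (1.24), Cd86 (1.11), Drosha (0.96), Capg (-0.77), Ppm1l (-0.87), P2rx7 (-1.47), St6galnac2 (-1.89), Nsg2 (-1.90), Hopx (-2.05), Khdc1a (-2.07), Lad1 (-3.00) and Gsta4 (-3.12). All 42 called probe sets stayed called with the actin 3' minus 5' difference as a covariate, which called 71.

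Tconv cells in the NOD Treg sort are 1 candidate explanation of these differences, since 89% of the cells of 1 NOD sort were Foxp3+ per the labels. Cells with the RNA of the sorted CD25- Tconv can only shrink a change in NOD. Foxp3- cells that passed the CD25+ gate may differ from these, and an effect of such cells was not tested. Of the 20 differences, 8 were larger in size in NOD, 40% (95% interval 19.1% to 63.9%). This argues against cells like the sorted Tconv for these 8. The slopes over 1364 genes, 0.884 for NOD on B6g7 and 0.95 for B6g7 on NOD, both lie below 1 and decide nothing. The 12 genes with the larger change in B6g7 would need a median share of 97.9% Tconv cells (68.2% to 100%). The lowest Foxp3+ share of a NOD sort was 89% per the labels, which argues against cells like the sorted Tconv as the only cause for these 12. These genes were picked for a called difference, so a smaller effect of Tconv cells was not tested. Foxp3 gives a share of 11.8%, but its difference between strains did not pass the test (-0.18 ± 0.28, adjusted p = 0.966), so this share is uncertain. Signal at background in 1 strain stays open: it holds for 20% (5.73% to 43.7%), namely A530021J07Rik, Afp, Irak1bp1 and Khdc1a, and the interval spans the bound of 25% set beforehand. A variant under the probes stays open for genes lower in NOD Treg but would not raise the NOD signal, as in Treg for Ntn4 (11.41 against 9.01), Ryr2 (9.05 against 6.04) and Il18r1 (11.33 against 9.54), and a difference in biology between the strains, which the design names, was not tested.

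Of the probe sets lower in NOD in both Tconv and Treg, some may be lower because NOD carries sequence variants under probes designed on B6 sequence. Beyond a log2 change of -1 in both there were 164 probe sets, for 146 genes. Other probe sets of a gene counted here only with a mean log2 level of at least 6.43, the median over probe sets. In the 104 genes with such others the median was -1.75 for the called and -0.0553 (95% interval -0.15 to 0.0169) for the others. These others lay within 0.2 of no change in 45 genes and below -0.5 in 26, so a variant and a difference in RNA cannot be told apart for the genes lower in NOD as a set. A variant would not raise the NOD signal, yet 44.3% of the calls in Tconv and 49% of those in Treg were higher in NOD. This argues against it for the genes higher in NOD only. Calls of at least 2-fold were more often lower in NOD, with 333 lower and 201 higher in Tconv, and 346 lower and 232 higher in Treg. In the genes higher in NOD the other probe sets also had a small median, 0.10 (0.02 to 0.20, called ones 1.47, 64 genes). Differing probe sets of a gene thus do not by themselves point to a variant. Other called probe sets of a gene were retained in both comparisons.

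B cells in the CD25+ sort could raise the B cell and MHC class II transcripts that were higher in Treg, such as H2-Aa (1.65) and Cd79b (0.79), although the sort removed cells with B220. Over Cd79a, Ms4a1, Fcer2a, Cd22, Blk and Cr2 the median change was -0.0148 (lowest -0.12, highest 0.15), so these 6 genes showed no rise. They were chosen after the result was seen and include none of the B cell markers called higher. The test therefore cannot decide whether B cells were a source. The mean log2 levels of these 6 genes in Tconv and Treg were 5.68 and 5.63, 6.69 and 6.72, 5.65 and 5.54, 8.38 and 8.25, 6.73 and 6.89, and 6.69 and 6.71. Of the 22 B cell markers 4 are also members of another list, and RNA of Treg cells themselves or of dendritic cells (2 of 12 markers higher, set test adjusted p = 0.059) was not tested as the source, though the sort took CD4+ cells without CD11b and B220.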

How the results depend on the processing

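Of the alternatives in this part, the fits without the 4 arrays numbered replicate 1 and with the actin covariate were chosen only after the result was seen. Comparisons are given here in the order B6g7, NOD, average over strains, difference between strains, strains in Tconv and strains in Treg, with 1519, 1443, 2632, 42, 1333 and 1468 called probe sets. Repeated quantile normalization, median centring and the trend and robust variance model moved none of these counts by over 1.5 times, and the scalings moved the median change by at most 0.0119 and 0.00773. Of the calls shared with the scalings, the filter, the variance model, the weights, the replicate block, the covariate and the fits without arrays, 0 changed direction. The array weights, from 0.352 (B6g7 Tconv replicate 3) to 3.98 (B6g7 Treg replicate 2), gave 3460 for B6g7 and 4796 for the average, of which 51.3% and 50.1% were higher instead of 60.4% and 59%, and 79 for the difference, 2181 for Tconv and 2361 for Treg; the cause was not tested. The replicate block gave 2286 for B6g7, 2362 for NOD, 89 for the difference and 2124 for Tconv; the cause was not tested beyond the correlation of same-numbered arrays. The actin covariate gave 2496, 2225, 4138, 71, 2077 and 2340, and all calls made without it were kept. Without the 4 arrays numbered replicate 1 there were 1150, 1133, 2356, 31, 1082 and 1184, of which 1015, 981, 1964, 26, 944 and 1013 were shared. With the arrays of the compared groups alone, so with fewer arrays for the spread, 976 were called for B6g7 and 976 for Treg. A 2-fold minimum, which can only remove calls, left 547, 512, 495, 534 and 578 for all but the difference, where it left the count within 1.5 times. The ratio of mean intensities of at least 2-fold, with no test, gave 592, 545, 508, 112, 588 and 634. For the difference, 17 were called among probe sets above the median level, all among the 42; the cause was not tested. The other comparisons stayed within 1.5 times there, with 1240, 1171, 2094, 1021 and 1096 calls shared.

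Leaving out each array in turn gave 1057 to 1503, 985 to 1552, 2180 to 2728, 27 to 38, 945 to 1439 and 1027 to 1505 called probe sets. The correlation of the Treg to Tconv changes between strains was 0.645 without NOD Treg replicate 1 and 0.786 without NOD Tconv replicate 1, and 0.884 to 0.913 over called genes. It was 0.672 over all probe sets, and 0.885 over called ones, or 0.915 above the median level; the cause was not tested. Of 695 values of named genes 0 reversed under the scalings, the variance model, the weights, the replicate block, the covariate or the fits without arrays, nor did any of the 558 and 469 that the filter and the fits of 2 groups allow; 656 kept their side of the threshold with the replicate block and 653 without the arrays numbered replicate 1. Of the called named genes, 65 of 73, 61 of 68, 76 of 80, 14 of 20, 35 of 50 and 36 of 45 passed in all 12 fits without 1 array. Of the 44 list calls 39 were kept with the mean of all probe sets of a gene, 44 with the replicate block, 42 above the median level, 14 with an estimated correlation, 37 with fry, 41 without NOD Treg replicate 1 and 41 without the arrays numbered replicate 1; 0 reversed.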

Other observations

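Of the tests in this part, the fit with the actin covariate and the splits within replicate numbers were chosen only after the result was seen. Averaged over both strains, 1 of 29 cell cycle genes was higher, Tk1 (0.36, adjusted p = 0.012), and 0 were lower in Treg than in Tconv, by either adjustment (set test adjusted p = 0.576). Of 31 interferon response genes 4 were higher, Ifitm3 (1.68), Isg20 (0.94), Usp18 (0.87) and Ifi27l2a (0.70), and Oas2 (-0.38) was lower; adjusted over the list alone, 8 were higher and 2 lower (set test adjusted p = 0.0143, adjusted p = 0.622 with an estimated correlation). Of 13 candidate genes of Idd regions, Ctla4 (3.42), Tnfrsf9 (1.32), Tnfrsf1b (1.24) and Vav3 (0.79) were higher and Il21 (-1.0) lower, with 5 and 2 adjusted over the list alone. The set test gave an adjusted p of 0.00818, which did not hold (adjusted p = 0.139 with an estimated correlation). In the difference between strains, 11 further genes had a called probe set that was not their brightest, and those named here were chosen after their values were seen. Matn2 (-3.45), Cybrd1 (2.61), Greb1 (2.40), Klf12 (2.13), Tnnt2 (-1.79) and Hdac9 (-1.40) each had a dim level in at least 1 group, so the sizes are uncertain. Gsto1 (-1.53, adjusted p = 0.0035) was not dim, with its lowest group mean at 7.63 in B6g7 Tconv.

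Of 9 plasma cell markers Xbp1 (0.99) and Irf4 (0.99) were higher (2 adjusted over the list alone, set test adjusted p = 0.172). Of 7 CD8 T cell markers Eomes (1.24) was higher and Crtam (-0.38) and Gzmk (-0.24) lower (1 and 2 adjusted over the list alone, set test adjusted p = 0.554). Of 12 dendritic cell markers Tcf4 (0.65) and Cst3 (0.42) were higher (3 adjusted over the list alone, set test adjusted p = 0.059). Of 12 erythroid and platelet markers Car2 (-0.41) was lower (1 adjusted over the list alone, set test adjusted p = 0.593). The monocyte, neutrophil and stromal lists gave set test adjusted p of 0.94, 0.983 and 0.94. None of 4 sex-linked genes was called, with Xist at 0.19 (adjusted p = 0.156), and this list was too short for a set test. Between strains, Cst3 was higher in NOD Tconv (1.11, adjusted p = 7.16e-04) and NOD Treg (0.60, adjusted p = 0.0454, passing in 3 of 12 fits without 1 array), and Bank1 was lower in NOD Treg (-1.03, adjusted p = 0.00478).

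Both strains carry the same MHC haplotype, so a hypothesis was that genes of the H2 region, from H2-Ke6 to H2-M3, differ between them less often than other genes. Of 121 measured genes of the region 2 were called in Tconv or Treg (1.65%), against 818 of 18072 other genes (4.53%). The odds ratio of 0.355 (95% interval 0.0424 to 1.31, Fisher's exact p = 0.182) leaves the hypothesis open. The called genes were H2-Ob, lower in NOD Tconv (-0.87, adjusted p = 0.0025; in Treg -0.22, adjusted p = 0.725), and H2-Q2, higher in NOD Tconv from a dim level (1.61, adjusted p = 8.42e-04; in Treg 0.77, adjusted p = 0.103).

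Other splits of the arrays were fitted in the same way. In the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. There, 1 of 10 splits, the real one, gave as many calls in each of B6g7 (1519, highest other 1), NOD (1443, highest other 0), Tconv (1333, highest other 0) and Treg (1468, highest other 0). For the averaged change 1 of 100 splits within strains gave as many calls, the real one with 2632. The highest other gave 2530 and the next 37. For the difference between strains 2 of 100 reassignments of the residuals gave as many as the real 42. There the highest other gave 4465 and the next 0. Since 1 other grouping of the arrays came near or above the real counts, these shares do not exclude chance. Both high values come from the same split, which sets the 6 arrays of lowest actin 3' minus 5' difference (2.66 to 3.84: Tconv replicates 1 and 2 and Treg replicate 1 of both strains) against the other 6 (4.25 to 4.70). The arrays thus have a structure that goes with this difference; whether RNA quality, amplification or a batch lies behind it was not tested. With the actin covariate 4138 and 71 probe sets were called in these comparisons. These splits exchange arrays across replicate numbers, although the numbers pair several groups by the data, if not by the labels. With exchanges only within a number, 1 of 32 splits gave as many calls for the averaged change (highest other 42), and 1 of 100 reassignments for the difference (highest other 0). Such exchanges always leave arrays of each number on both sides. The split along the actin difference sets every replicate 1 array on the same side, so they cannot draw it. Their low counts therefore do not exclude that structure or chance.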
